A study of Mus musculus with 13 samples.

How the data were processed

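The 13 libraries are single-cell 3' gene expression profiles of endoderm from mouse embryos of a C57BL/6 and C3H cross, at 7 stages from 9 to 27 somite pairs and in 2 batches, which the labels number. Per the labels, tissue was dissociated with trypsin, stained with an antibody to Epcam and sorted, and dead cells taking up DAPI were excluded. The deposited values are counts: each matrix holds whole numbers of UMIs per gene and barcode for 27998 genes, with no normalization by the authors. The authors' notes name Cell Ranger 6.0.0 and mm10. Per the file headers, version 6.0.0 made 5 libraries, 12SS to 24SS of batch 1, and version 3.0.1 made the other 8. All files mapped to a sample, and 0 were left over. The labels do not say whether libraries of a stage came from separate embryos or pools, so p-values measure the spread between these libraries.

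Barcodes numbered 4924 to 14582 per library, with a median of 10996 to 25007 UMIs and total counts of 120638039 to 192938823 UMIs. Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept, 102650 of 124210. Doublets were predicted per library with Scrublet in scanpy 1.11.5 at its automatic threshold. Where that marked under 0.5% of a library, at 21SS batch 1 and 27SS of both batches, the top scores were removed at 0.8% per 1000 barcodes. In all 4261 cells were removed, 3.35 to 7.24% of a library, and 98389 were kept. Counts were scaled to the same total per cell and logged. Mitochondrial, haemoglobin, ribosomal protein, cell cycle, Xist and Y-linked genes were left out, and 2000 variable genes were reduced to 40 components. Cells were clustered on 15 neighbours by the Leiden method of igraph at resolution 1, giving 42 clusters, without integration of batches.

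Clusters were named from marker lists, by a rule whose thresholds were set once the clusters had been made. A name needed a mean marker score of at least 0.3 and at least 3 markers at 1.5-fold or more over all other cells, with a pseudocount of 5 CPM, each seen in at least 10% of cells. It also needed as many of its markers among the 10 leading genes, each seen in at least 25% of cells, as any other name had. Clusters with a median under 33.3% of their library's median UMIs needed at least 1 marker there. After the clusters were seen, genes were added that a name could not do without: Nkx2-1 for lung-like and thyroid-like cells, Cdx2 for midgut-like and hindgut-like cells, Pdx1 for pancreas-like cells, and Rhox5, Cubn or Amn for visceral endoderm-like cells. Clusters without a name counted as gut endoderm of no named region, 6 of the 42, where Epcam was seen in at least 90% of cells and Foxa1 or Foxa2 in at least 20%. Other clusters without a name held 0.0779 to 1.90% of kept cells per library. A marker of a class is no finding about that class, and its changes are given as values within a class already chosen.

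UMIs were summed per library over all gut endoderm cells and over each class with at least 50 cells. Sums were fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, the quasi-likelihood F-test of the slope on somite number, and Benjamini-Hochberg adjusted p under 0.05. Changes are log2 changes over the span of a fit's own libraries: 18 somites in pooled, hindgut-like, pharynx-like and thyroid-like cells, 15 in midgut-like, oesophagus and stomach-like, bile duct-like and pancreas-like cells, and 12 in liver-like and lung-like cells. A class was fitted with at least 6 libraries over 4 stages. Differences between classes were tested as an interaction with library as a block, neighbouring stages as contrasts with stage as a factor, and batches with stage as a factor. DESeq2 1.42.0 was run beside it. Named genes are the 10 up and 10 down with the largest change in the pooled fit, 6 and 6 in a class fit, 5 and 5 in an interaction and 3 and 3 in a step. They pass the test with a mean of at least 20 CPM (in an interaction, in the class with the larger change) and, in the stage fits, have a Spearman correlation of the same sign in each batch that has 3 stages or more. Named too are up to 4 members per list with the lowest p, and Epcam. In the batch comparison and the classes of the closing section 6 and 6 were named by size, a choice made after the data were seen. Members that went against their list, and the last members of short lists, were named after their values were seen.

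In total 29 gene lists fixed in advance were tested in each fit where at least 4 members were measured, with camera of limma 3.58.1 on log-CPM with a prior count of 2. The preset correlation was 0.01, and camera with an estimated correlation and fry stand beside it. fry asks whether the genes of a set move, on balance, one way, and compares it with no other genes. Only the 4 calls named for pancreas-like cells hold with an estimated correlation. Shares of 21 classes were correlated with somite number by 2-sided permutation tests with 100000 resamples, exact within batches, in scipy 1.17.1 and numpy 2.4.6. The smallest p the resamples can give is 1e-05. Intervals of shares are 95% Wilson intervals, and like the floor of 3 counts they cover counting error only. For a gene with no UMI in a class at its first stage, the fold is a lower bound: the mean CPM of the last stage over 3 counts in the summed UMIs of the first.

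Batch numbers pair libraries of a stage by the labels. Checked over the 6 stages, correlations between batch 1 libraries of their deviations from the stage mean ran from 0.459 to 0.833, with a median of 0.677, so libraries of a batch share a component. Counts with batch as a block stand beside a result where it moved them by over 1.5 times. It ended the calls of 13 genes tested in the class fits, of which those counted as list members in the report are named there. Libraries of a stage were not copies of each other: the chi-square per gene between them was 169 to 498. The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the stage fits 99 to 100% of 4-fold changes and 33% (pooled) to 98% (liver-like) of 2-fold changes were found, with 3 to 16 unchanged genes called.

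The groups, comparisons, lists, markers, the rule for named genes and the alternatives below were set before the data were examined. These alternatives were RLE size factors, no filter on low counts, DESeq2, batch as a block, a filter of 2000 genes and 5% mitochondrial UMIs, doublets kept, equal numbers of cells per library, all kept cells, stage as ranks, clustering at resolution 0.5 and 2 or without the genes called along stage (31 clusters), and leaving out each library in turn. Gene positions are from GENCODE M21. Haemoglobin, mitochondrial, Xist and Y-linked genes and genes without a symbol of their own were not named.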

Results

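The series profiled single cells of the mouse endoderm, the inner germ layer that forms the gut tube and its organs, over 7 stages counted in somite pairs (SS). Cells had been stained for Epcam, an epithelial surface protein, and sorted, and the mRNA of each cell was counted by droplet sequencing. There was 1 library at 9SS, from batch 1, and 1 library per batch at each of 12SS, 15SS, 18SS, 21SS, 24SS and 27SS, 13 in all. In batch 1, the libraries from 9SS to 27SS held 184869337, 192938823, 160132949, 164658333, 125316173, 151385603 and 120638039 UMIs (unique molecular identifiers, 1 per captured mRNA). The batch 2 libraries from 12SS to 27SS held 154204755, 149424183, 172813139, 174390699, 148546147 and 123025483 UMIs. After filtering, 98389 cells remained, of which 68694 were gut endoderm by their markers. Gut endoderm made up between 49.8% (12SS batch 2) and 87.9% (9SS) of the cells kept. Classes of cells are called "like" a region from marker genes alone. Changes are log2 changes from the first to the last stage of a fit along its slope on somite number, and coordinates are on GRCm38.

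The first comparison asks what changed with stage in sorted gut endoderm as a whole, as the series follows how endoderm lineages develop. Among genes with a mean of at least 20 CPM, the largest rises were mostly in genes of secreted blood proteins. Apoa2, an apolipoprotein (ENSMUSG00000005681, chromosome 1, 171225054 to 171226379), changed by 6.32 (SE 0.78, adjusted p = 0.000155), from 2.05 CPM at 9SS (n = 1) to 242 ± 229.5 CPM (SD, n = 2) at 27SS, and Afp, alpha-fetoprotein, by 3.76 (SE 0.66, adjusted p = 0.00203), from 34.9 CPM at 9SS (n = 1) to 739.5 ± 694 CPM (SD, n = 2) at 27SS. Trf, transferrin, rose by 4.61 (SE 0.51), Itih2 and Ambp, a chain of the inter-alpha-trypsin inhibitor family and the precursor of another, by 5.60 and 4.63, Serpina1b and Serpina1a, alpha-1 antitrypsins, by 3.61 and 2.97, and Fgb, a fibrinogen chain, by 3.02. Slc38a5, an amino acid transporter, and Serpinf2, the plasmin inhibitor, rose by 4.37 and 2.50. At 27SS liver-like cells were 3.46% (95% interval 2.81 to 4.25%) of gut endoderm in batch 1 and 15.6% (95% interval 14.4 to 17.0%) in batch 2, and Apoa2 stood at 80.2 and 405 CPM in these libraries.

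Genes that fell in pooled gut endoderm included Car4, a membrane carbonic anhydrase (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044), at -3.37 (SE 0.31, adjusted p = 1.31e-05), from 861 CPM at 9SS (n = 1) to 84.6 ± 24.4 CPM (SD, n = 2) at 27SS, and Spink1, a trypsin inhibitor, at -3.84 (SE 0.68, adjusted p = 0.00226). Myl3, a myosin light chain, changed by -3.65 (SE 0.17, adjusted p = 7.33e-08). S100g, a calcium-binding protein, fell by 3.96, Phlda2, an imprinted growth gene, by 3.15, Apela, a ligand of the apelin receptor, by 2.28, and Gpx2, a glutathione peroxidase, by 2.26. The basement membrane gene Nid2 and the surface proteins Dpp4 and Podxl dropped by 2.08, 2.05 and 1.95. Epcam, the sorted antigen, stood at 810.5 CPM at 9SS and 598 CPM at 27SS and did not pass (log2 change -0.43, adjusted p = 0.0941). It passed with batch as a block, at -0.37 and adjusted p = 0.0126, and without 24SS batch 1. In all, 2416 of 16617 genes changed by edgeR over the 13 libraries, 1438 up and 978 down. With batch as a block there were 4316, in batch 1 alone 3470, in batch 2 alone 1229, and without the 9SS library 1504. The call of Serpinf2 ended without 9SS (adjusted p = 0.0705) or 27SS batch 2 (adjusted p = 0.0865).

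Of 29 gene lists, 8 moved along stage in pooled gut endoderm (13 with batch as a block, and 0 of the 8 with an estimated correlation, adjusted p from 0.0545 to 0.625). For the liver list, 7 of 14 rose and 1 fell (7 and 1 adjusted over the list alone), with Alb, albumin, at 8.55 and Fga at 3.30, and Ttr, the thyroid hormone carrier, as the member that fell (adjusted p = 0.000534). In the pancreas and bile duct list 7 of 13 rose and 0 fell (7 and 1 adjusted over the list alone), among them Ptf1a at 7.09 and Pax6 at 4.40 (adjusted p = 6.28e-05). Cpa1, a digestive enzyme, had no UMI at 9SS and was at least 197-fold higher at 27SS. In the G2/M list 14 of 20 fell (17 adjusted over the list alone), with Kif23 at -0.76 and Plk1 at -0.64 (adjusted p = 8.1e-11), and in the S phase list 7 of 20 fell (9 adjusted over the list alone), with Mcm4 at -0.59 (adjusted p = 6.28e-05). In the early embryonic and pluripotency list 5 of 15 fell (8 adjusted over the list alone), with L1td1 at -1.74 and Lin28a, an inhibitor of let-7 maturation, at -1.38 (adjusted p = 0.000691). The pan-endoderm list moved down (adjusted p = 0.00250). In the cholesterol synthesis list 2 of 17 rose (1 adjusted over the list alone), Sc5d and Lss (adjusted p = 0.000534), and both calls ended without 9SS (adjusted p = 0.0664 and 0.137), either 12SS library, 24SS batch 2 or 27SS batch 2, that of Lss also without 15SS batch 2 or either 21SS library. The ribosomal protein list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 4 had an unadjusted p under 0.05 and 3 passed by DESeq2 (adjusted p = 0.00250).

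**Figure D1:**
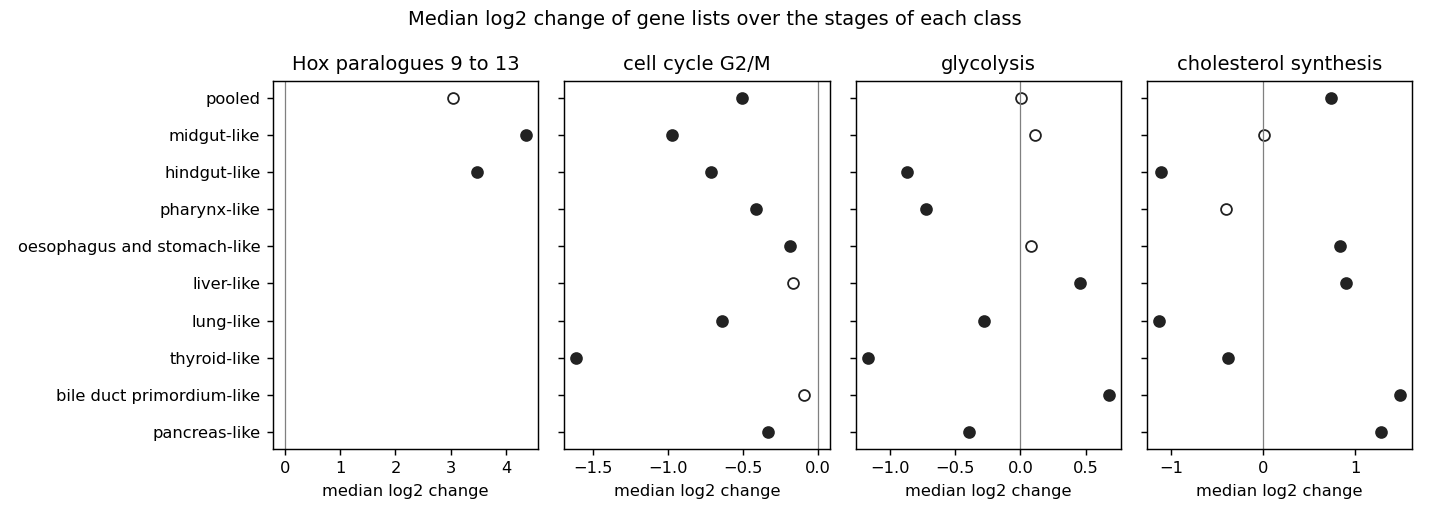
Median log2 change from the first to the last stage of each fit (x axis) of 4 gene lists in the pooled fit and the 9 class fits (y axis). Each point is 1 fit, filled where camera with the preset correlation of 0.01 gave an adjusted p under 0.05 and open where it did not. The Hox list was measured in 3 fits. The G2/M list stood below 0 in the 10 fits, and the cholesterol synthesis list ranged from -1.13 in lung-like to 1.49 in bile duct primordium-like cells.

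Class by class, the next fits ask what changed within a region, apart from changes in the mix of regions. Midgut-like cells carry Cdx2, Foxa3 and Isx and were fitted in 12 libraries from 12SS to 27SS. Their posterior Hox genes, which mark position along the body axis, rose together. Car4 fell most, by 4.38 on the log2 scale (SE 0.16, adjusted p = 1.48e-10), from 741 CPM at 12SS (n = 2) to 38.5 ± 2.51 CPM (SD, n = 2) at 27SS. Eps8l2, a regulator of actin (ENSMUSG00000025504, chromosome 7, 141338880 to 141363020), rose by 2.78 (SE 0.18, adjusted p = 2.01e-07), from 8.75 CPM at 12SS (n = 2) to 66.6 ± 13.3 CPM (SD, n = 2) at 27SS. Cpne8, a copine, rose by 2.79, Ambp by 2.71, Stmn2, which destabilises microtubules, by 2.22, Bcl2, which blocks apoptosis, by 2.07, and Ntng1, a netrin, by 1.87. S100g fell by 2.65, Myl3 by 2.60, Spink1 by 2.49, Ttr by 2.48 (1051 to 199.7 CPM) and Emb, a partner of lactate transporters, by 2.33. The cells came mostly from cluster 16 in the 12SS and 15SS libraries of batch 2 and from clusters 0, 6 and 15 in the others. Of 13851 genes, 2474 changed, 1282 up and 1192 down. Batch 1 alone gave 1772 genes and batch 2 alone 1348.

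Among 29 lists, 7 moved in midgut-like cells, none of them with an estimated correlation by camera (adjusted p from 0.0521 to 0.151) (of the 29, fry called 11). Of the Hox paralogues 9 to 13, 10 of 10 rose (10 adjusted over the list alone), with a median of 4.37 (adjusted p = 9.61e-09). Hoxc9 (ENSMUSG00000036139, chromosome 15, 102976439 to 102985099) changed by 4.37 (SE 0.47, adjusted p = 1.55e-05), from 0.943 CPM at 12SS (n = 2) to 20.1 ± 3.38 CPM (SD, n = 2) at 27SS, Hoxa10 by 4.37 and Hoxa9 by 2.64. Hoxd10 had no UMI at 12SS and was at least 59.0-fold higher at 27SS. Of Hox paralogues 5 to 8, 10 of 11 rose (11 adjusted over the list alone), with Hoxc6 at 3.72, Hoxc5 at 1.89 and Hoxa6 at least 21.4-fold higher at 27SS (adjusted p = 3.49e-10). The posterior gut list shares Hox genes with both, and 11 of 14 rose and 1 fell (12 and 2 adjusted over the list alone), the faller being Cdx1 (adjusted p = 3.49e-06). For cell division, 20 of 20 fell (20 adjusted over the list alone) on the G2/M list, with Plk1 at -1.22 and Aurka at -1.05 (adjusted p = 7.91e-22). On the S phase list 13 of 20 fell (14 adjusted over the list alone), with Uhrf1 at -1.16 and Rrm2 at -1.15 (adjusted p = 1.7e-08). The early embryonic and pan-endoderm lists also moved down (adjusted p = 0.00191 and 0.0149). Without the 12SS and 15SS libraries of batch 2, 11 lists moved.

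Hindgut-like cells, named from Cdx and posterior Hox genes, were fitted in 8 libraries, 7 of batch 1 and 27SS of batch 2. Cluster 3 held 45.0% of them at 9SS and 66.9% and 100% at 27SS, and clusters 18 and 29 the others, so the mix of clusters was not constant. At resolution 2, cluster 55, of no named region, had hindgut markers and Dapl1, Hoxd13 and Ntm among its leading genes. It held 0 cells at 9SS and 124 and 51 at 27SS, so rises of these genes may be those of late cells. Dapl1 (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020) rose by 6.06 (SE 0.54, adjusted p = 0.000174), from 2.34 CPM at 9SS (n = 1) to 101 ± 87.5 CPM (SD, n = 2) at 27SS, Eps8l2 by 5.05 and Ntm, neurotrimin, by 4.54. Npnt rose by 4.00, Oxct1 by 3.69 and Aldh1a2 by 3.68. At 24SS and 27SS they stood at 109, 54.8 and 43.9 CPM, against 122, 56.3 and 28.2 CPM in other germ layers. Nepn, nephrocan, fell by 4.27 (SE 0.38, adjusted p = 0.000161). Sox17 fell by 3.40, Myl3 by 3.33, Gpx2 by 3.33, Cited1 by 3.12, and Hoxaas3, a non-coding RNA of the Hoxa cluster, by 3.10 (adjusted p = 0.0488). Of 13795 genes, 2313 changed, 1348 up and 965 down, and batch 1 alone gave 2718. Leaving out 27SS batch 1 gave 1236 and 12SS batch 1 gave 1281, and the call of Hoxaas3 ended without any 1 of the 7 batch 1 libraries (adjusted p = 0.154 without 27SS batch 1).

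In hindgut-like cells 11 of 29 lists moved, none with an estimated correlation (adjusted p from 0.327 to 0.775). Of Hox paralogues 9 to 13, which include naming markers of the class, 6 of 15 rose and 1 fell (10 and 2 adjusted over the list alone), with Hoxa13 at 4.61 and Hoxd13 at 3.60. Hoxd12 and Hoxc12 had no UMI at 9SS and were at least 276-fold and at least 65.8-fold higher at 27SS, and Hoxd9 was the faller (adjusted p = 0.00851). On the Wnt list 2 of 20 rose and 7 fell (3 and 8 adjusted over the list alone), with Lgr5, a receptor for R-spondins, at -4.24, Wnt6 at -2.47 and Notum, which inactivates Wnt proteins, at -2.46 (adjusted p = 0.0223). At 9SS other germ layers held Wnt6 at 895% and Notum at 158% of the level here, so free RNA is not excluded. On the small intestine list 1 of 9 rose and 4 fell (1 and 4 adjusted over the list alone), with Pyy, a gut hormone, at -4.23 and Cdx1 at -3.41 (adjusted p = 0.0223). Glucose metabolism moved down: 6 of 17 fell (10 adjusted over the list alone) on the glycolysis list, with the glucose transporters Slc2a1 and Slc2a3 at -2.02 and -1.37 (adjusted p = 0.000238), as did the hypoxia list (adjusted p = 0.00350). The imprinted list moved up (adjusted p = 0.0171). The early embryonic, cholesterol synthesis, S phase and ribosomal protein lists also moved down (adjusted p = 0.0223, 0.000194, 0.00357 and 0.00397). The G2/M list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 9 had an unadjusted p under 0.05 and 6 passed by DESeq2 (adjusted p = 0.00028).

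Pharynx-like cells, named from Pax9, Pax1 and other foregut genes, were fitted in 8 libraries, 7 of batch 1 and 27SS of batch 2. They lay mostly in cluster 14 from 9SS to 15SS and in cluster 12 from 18SS. Anterior Hox genes rose and glucose metabolism fell. Hoxb3os, a non-coding RNA of the Hoxb cluster (ENSMUSG00000084844, chromosome 11, 96343072 to 96354691), rose by 3.68 (SE 0.60, adjusted p = 0.00339) and Rarres1, a retinoid-responsive gene, by 3.67. Pmp22, a myelin membrane protein, rose by 3.31, Mfap4, a matrix protein, by 3.17, Sfrp2, a secreted Wnt modulator, by 3.14, and Shisa2 by 3.10. At 24SS and 27SS Pmp22 stood at 48.0 CPM against 69.3 CPM in other germ layers, and Mfap4 at 43.7 CPM against 42.2 CPM in other germ layers. Slc2a1, a glucose transporter, fell by 2.45 (SE 0.16, adjusted p = 2.07e-05), from 660.5 CPM at 9SS (n = 1) to 109.9 ± 1.14 CPM (SD, n = 2) at 27SS. Upp1, of uridine breakdown, fell by 3.55, Sp5, a target of Wnt signalling, by 2.72, Kitl, the ligand of Kit, by 2.50 and Car4 by 2.47. Of 13224 genes, 1462 changed, 848 up and 614 down, and batch 1 alone gave 1685. Leaving out 27SS batch 1 gave 804, 12SS batch 1 gave 836 and 9SS gave 886, and Rarres1 lost its call without 27SS batch 1 (adjusted p = 0.0545).

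Of 28 lists tested in pharynx-like cells, 6 moved, none with an estimated correlation (adjusted p from 0.553 to 0.690), and 4 moved without 27SS batch 1. Of Hox paralogues 1 to 4, 8 of 9 rose (8 adjusted over the list alone), with Hoxa3 at 5.36, Hoxb4 at 4.75 and Hoxa2 at 4.59 (adjusted p = 1.33e-08). Hoxa4 had no UMI at 9SS and was at least 11-fold higher at 27SS, and the list's median was 4.20, or 3.46 with Hoxa4 at that bound. On the glycolysis list 10 of 17 fell (11 adjusted over the list alone), with Pfkl at -1.02, Aldoa at -0.90 and Pkm at -0.69 (adjusted p = 5.76e-07). The hypoxia list moved down (adjusted p = 0.0107). On the G2/M list 5 of 20 fell (15 adjusted over the list alone), with Cenpf at -0.62 (adjusted p = 8.9e-07), and Plk1 was lost with batch as a block (adjusted p = 0.0566). The S phase list moved down with 0 of 20 members (7 adjusted over the list alone) passing by edgeR, of which 10 had an unadjusted p under 0.05 and 6 passed by DESeq2 (adjusted p = 0.0275). The ribosomal protein list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 3 had an unadjusted p under 0.05 and 2 passed by DESeq2 (adjusted p = 0.0292).

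Cells like oesophagus and stomach were named from Sox2, Sox21, Osr1 and Gata4 and were fitted in 11 libraries from 12SS to 27SS. They came from cluster 19 in the 12SS and 15SS libraries of batch 2 and from cluster 4 in the others. The pharyngeal foregut and liver lists fell, while the Notch and cholesterol lists rose. Ly6h, a surface protein (ENSMUSG00000022577, chromosome 15, 75551268 to 75567255), rose by 3.46 (SE 0.64, adjusted p = 0.00346), from 4.51 CPM at 12SS (n = 1) to 139 ± 26.1 CPM (SD, n = 2) at 27SS. Eps8l2 rose by 2.79, Ppp2r2b, a phosphatase subunit, by 2.36, Cldn3, of tight junctions, by 2.33, Mt2, a metallothionein, by 2.11 and Plk2, a kinase, by 1.99. Pyy fell by 4.27 and Spink1 by 4.21, from 301 CPM at 12SS (n = 1) to 10.0 ± 0.861 CPM (SD, n = 2) at 27SS. Ripply3 fell by 3.08, Phlda2 by 2.91 (other germ layers at 12SS held 291% of its level), Ttr by 2.89 and Peg10, an imprinted gene, by 2.82. Of 13020 genes, 1020 changed, 595 up and 425 down. Batch 1 alone gave 372 and batch 2 alone 576. Leaving out 12SS batch 2 gave 407, 15SS batch 2 gave 674 and 27SS batch 1 gave 592.

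Of 28 lists, 10 moved in these cells, none with an estimated correlation (adjusted p from 0.251 to 0.638), and 5 moved without 27SS batch 2. On the Notch list 5 of 12 rose (6 adjusted over the list alone), with Notch1 at 1.66, Dll1, a ligand, at 1.27, and the target Hes1 at 0.86 (adjusted p = 0.00301). On the cholesterol synthesis list 7 of 17 rose (13 adjusted over the list alone), with Msmo1 at 1.04 (adjusted p = 2.46e-08). On the pharyngeal foregut list 4 of 7 fell (4 adjusted over the list alone), with Nkx2-3 at -5.21 and Pax9 at -2.12 (adjusted p = 0.00690). Without 12SS batch 2 the call of Pax9 ended (adjusted p = 0.318), and in batch 1 alone Pax9 stood at 0.78 (adjusted p = 0.694). On the liver list 5 of 12 fell (7 adjusted over the list alone), with Apob, an apolipoprotein, at -4.22 and Tbx3 at -3.39 (adjusted p = 7.56e-06). At 12SS Apob stood at 33.5 CPM against 10.2 CPM in mesoderm-like cells of the library, and Tbx3 at 15.7 CPM against 14.9 CPM, while visceral endoderm-like cells, which carry Apob, became fewer with stage. In the list of the class itself, whose members also name it, 2 of 8 rose (3 adjusted over the list alone), Sox2 at 1.52 and Sox21 at 1.69 (adjusted p = 0.0357). The pancreas and bile duct list moved up (adjusted p = 0.0449), where Mnx1 and Onecut1 lost their calls without 12SS batch 2. The imprinted, early embryonic, S phase and G2/M lists also moved down (adjusted p = 0.0239, 0.00301, 0.0155 and 0.0277).

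Liver-like cells formed cluster 1, named from Afp, Alb, Ttr, Trf and other plasma protein genes, and were fitted in 10 libraries from 15SS to 27SS. Liver-like cluster 3 at resolution 2 held 403 cells at 15SS and 7 at 27SS of batch 1, and cluster 21 held 9 and 80, so early and late cells differ. Plasma protein genes rose, and epithelial junction genes fell as N-cadherin rose. Alb, albumin and a naming marker (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), rose by 5.12 (SE 0.29, adjusted p = 1.46e-08), from 13.7 CPM at 15SS (n = 2) to 495 ± 78.7 CPM (SD, n = 2) at 27SS. Trf, also a marker, rose by 4.59, Serpina6, which binds corticosteroids, by 4.33, Serpind1, a thrombin inhibitor, by 3.83, and H2-Q10, a secreted MHC class I protein, by 3.86. Cdh2, N-cadherin, changed by 3.82 (SE 0.22, adjusted p = 1.6e-08), from 4.58 CPM at 15SS (n = 2) to 65.0 ± 8.42 CPM (SD, n = 2) at 27SS. Epcam, the sorted antigen, fell by 0.81 (adjusted p = 0.0101), from 467 CPM at 15SS (n = 2) to 269 ± 35.6 CPM (SD, n = 2) at 27SS, and lost its call without 15SS batch 1 (adjusted p = 0.0714) or 27SS batch 2 (adjusted p = 0.0744). Pyy fell by 3.26, Enpp1 by 2.96, Flrt3 by 2.27 and Apela by 2.16. Mest, an imprinted gene, and Col1a2, a collagen, fell by 2.40 and 2.28, and at 24SS and 27SS Mest stood at 46.2 CPM against 765 CPM in other germ layers and Col1a2 at 17.8 CPM against 115 CPM in other germ layers. Of 12037 genes, 2074 changed, 1160 up and 914 down. Batch 1 alone gave 1431, batch 2 alone 1212, and leaving out 27SS batch 2 or 15SS batch 1 gave 1116 or 1367.

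Of 24 lists, 8 moved in liver-like cells, none with an estimated correlation (adjusted p from 0.0789 to 0.245), and fry called 13. On the liver list, whose members name the class, 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone), with Afp at 2.29, Fgb at 1.87 and Ttr as the faller (adjusted p = 1.79e-10). On the cholesterol synthesis list 12 of 17 rose (16 adjusted over the list alone), with Fdps at 1.26, Nsdhl at 1.24 and Mvd at 1.27 (adjusted p = 1.93e-08). On the glycolysis list 8 of 17 rose and 1 fell (8 and 1 adjusted over the list alone), with Pfkp at 1.83, Hk2, hexokinase, at 1.43, Pdk1, which holds pyruvate from the mitochondria, at 1.34 and Slc2a3 at -0.71 (adjusted p = 0.000134). On the hypoxia list 5 of 10 rose (6 adjusted over the list alone), with Ndrg1 at 2.31, Bnip3 at 1.55 and Vegfa, the vascular growth factor, at 1.01 (adjusted p = 0.00111). On the junction and keratin list 1 of 19 rose and 10 fell (1 and 11 adjusted over the list alone), with Krt7 at -1.48 and Grhl2, an activator of epithelial genes, at -1.78 (adjusted p = 0.00386). At 15SS other germ layers held Krt7 at 149% and Grhl2 at 338% of the level here, so free RNA is not excluded. The thyroid and lung, pan-endoderm and S phase lists also moved down (adjusted p = 0.00817, 0.00386 and 0.0233).

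Lung-like cells formed cluster 11, named from Nkx2-1, Irx1, Irx2, Irx3, Foxp2 and Etv5, and were fitted in 9 libraries from 15SS, with 1 library at that stage, to 27SS. Wnt7b and the Fgf list rose. Cholesterol, retinoic acid and division lists fell. Wnt7b, a Wnt ligand (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473), rose by 7.80 (SE 0.71, adjusted p = 7.04e-06), from 0.458 CPM at 15SS (n = 1) to 67.3 ± 21.1 CPM (SD, n = 2) at 27SS. Thbs1, thrombospondin, rose by 3.85 and Cldn3 by 3.19. The naming markers Etv5, Foxp2 and Nkx2-1 rose by 4.90, 3.71 and 3.46, and Nkx2-1 (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908) moved from 21.0 CPM at 15SS (n = 1) to 284 ± 6.96 CPM (SD, n = 2) at 27SS. Ttr fell by 3.65 (SE 0.30, adjusted p = 3.91e-06), from 284 CPM at 15SS (n = 1) to 22.1 ± 10.1 CPM (SD, n = 2) at 27SS. Upp1 fell by 3.70, Car4 and Car2, carbonic anhydrases, by 2.35 and 1.83, and Robo2, a receptor for Slit proteins, by 2.19. Prrx2, a homeobox gene of mesenchyme, fell by 2.84 and stood late at 12.2 CPM against 125 CPM in other germ layers. Of 11576 genes, 1779 changed, 953 up and 826 down. Batch 1 alone gave 632, while batch 2 held 4 lung-like libraries and was not fitted alone. Leaving out 27SS batch 2 gave 565, 27SS batch 1 gave 964 and 15SS batch 1 gave 1124.

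Of 26 lists, 12 moved in lung-like cells, none with an estimated correlation (adjusted p from 0.0502 to 0.601), and 7 moved without 27SS batch 1. On the thyroid and lung list, which shares markers with the class, 8 of 11 rose (9 adjusted over the list alone), with Sox9 at 3.01 (adjusted p = 1.49e-06). On the Fgf list 5 of 11 rose (6 adjusted over the list alone), with the feedback genes Spry2 and Dusp6 at 2.32 and 2.17 and the receptor Fgfr2 at 1.39 (adjusted p = 0.000489). On the cholesterol synthesis list 14 of 17 fell (16 adjusted over the list alone), with Cyp51 at -1.49, Msmo1 at -1.47 and Idi1 at -1.25 (adjusted p = 2.25e-10). On the retinoic acid list 1 of 11 rose and 5 fell (1 and 5 adjusted over the list alone), with Cyp26a1, which breaks down retinoic acid, at -4.78, Crabp1, which binds it, at -2.27, and Aldh1a3 as the riser (adjusted p = 0.00354). At 15SS cells of other germ layers held Crabp1 at 2620% of the level here, so free RNA is not excluded. The G2/M, small intestine, S phase, liver, early embryonic, glycolysis and pharyngeal foregut lists also moved down (adjusted p = 3.14e-11, 0.0274, 0.0185, 0.0230, 0.0185, 0.0356 and 0.0274). The ribosomal protein list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 5 had an unadjusted p under 0.05 and 2 passed by DESeq2 (adjusted p = 0.0345).

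Thyroid-like cells formed cluster 10, named from Nkx2-1, Pax8, Foxe1, Hhex and Bcl2, and were fitted in 8 libraries, 7 of batch 1 and 27SS of batch 2. At resolution 2, cluster 40, pharynx-like with thyroid markers, had Otx2 and Tnnt1 among its leading genes. It held 400 cells at 9SS and 5 at 27SS of batch 1. Thyroid-like cluster 14 held 446 and 126, so early and late cells may differ. Hspb1, a small heat shock protein (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563), rose by 4.56 (SE 0.51, adjusted p = 0.000291), Cdh13, a cadherin, by 4.51, and Hoxb3os by 4.36. Eps8l2 rose by 3.86, Rdh10 by 3.80 and Plagl1 by 3.66. Otx2, a homeobox gene of the anterior embryo (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), fell by 3.92 (SE 0.29, adjusted p = 3.57e-05), from 116 CPM at 9SS (n = 1) to 5.01 ± 3.40 CPM (SD, n = 2) at 27SS. Spink1 fell by 6.55, Tnnt1 by 4.65, Has2 by 4.00, Hist1h1b by 3.59 and Cpm by 2.93. Of 11701 genes, 1961 changed, 999 up and 962 down, and batch 1 alone gave 2511. Leaving out 9SS gave 1112 and 12SS batch 1 gave 1128.

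Of 24 lists, 10 moved in thyroid-like cells, none with an estimated correlation (adjusted p from 0.219 to 0.670), and 5 moved without 24SS batch 1 and 6 without 27SS batch 1. On the G2/M list 19 of 20 fell (20 adjusted over the list alone), with Top2a at -2.19 and Plk1 at -2.11 (adjusted p = 6.32e-19). On the glycolysis list 11 of 17 fell (12 adjusted over the list alone), with Slc2a1 at -2.87 and Pfkl at -1.59 (adjusted p = 2.39e-07). On the hedgehog list 5 of 10 rose (6 adjusted over the list alone), with Shh at 2.00 and Hhip at 6.36 (adjusted p = 0.0155). Of Hox paralogues 1 to 4, 5 of 6 rose (5 adjusted over the list alone), with Hoxa2 at 7.73 and Hoxb3 at 4.88 (adjusted p = 0.000357). On the pharyngeal foregut list 4 of 7 fell (4 adjusted over the list alone), Otx2 among them (adjusted p = 0.0181). With batch as a block Ptch1 of the hedgehog list and Pax1 of the foregut list lost their calls (adjusted p = 0.0553 and 0.0623). The oesophagus and stomach list moved up (adjusted p = 0.0393). The S phase, cholesterol synthesis, hypoxia and ribosomal protein lists also moved down (adjusted p = 0.000357, 0.0237, 0.0200 and 0.00782).

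Cells like the bile duct primordium formed cluster 13, named from Sox17, Pdx1, Hhex and Onecut1, and were fitted in 9 libraries from 12SS to 27SS, with 1 library at 27SS. Of the 12SS and 15SS cells of batch 2, 744 of 837 and 787 of 928 lay at resolution 2 in a liver-like cluster, apart from most later cells, so the fit compares different cells early and late. The cholesterol and Fgf lists rose. Rbms3, which binds RNA (ENSMUSG00000039607, chromosome 9, 116572746 to 117629913), rose by 4.68 (SE 0.41, adjusted p = 8.7e-05), from 4.04 CPM at 12SS (n = 2) to 89.8 CPM (n = 1) at 27SS. Cited1 rose by 3.66, Adamts9, a matrix protease, by 3.45, Itih2 by 3.27, Etv5, a target of Fgf signalling, by 3.16 and Ambp by 3.06. Apob fell by 4.06 (SE 0.48, adjusted p = 0.000619) and Apoa1 by 3.04. Pyy fell by 5.32, Car2 by 3.51, S100g by 3.17 and Spink1 by 2.85. Of 11199 genes, 551 changed, 356 up and 195 down, and 1065 with batch as a block. Batch 2 alone gave 658, leaving out 12SS and 15SS of batch 2 gave 1724, and batch 1 held 3 libraries and was not fitted alone. Leaving out 27SS batch 2 gave 221 and 24SS batch 2 gave 300, and Pyy lost its call without 27SS batch 2 (adjusted p = 0.0636) or 12SS batch 2 (adjusted p = 0.0604).

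Of 24 lists, 8 moved in these cells, none with an estimated correlation (adjusted p from 0.0878 to 0.589), and 5 moved without the 12SS and 15SS libraries of batch 2. On the cholesterol synthesis list 12 of 17 rose (15 adjusted over the list alone), with Lss at 2.06, Insig1, which restrains the pathway, at 1.95 and Fdps at 1.82 (adjusted p = 5.45e-14). On the Fgf list 3 of 9 rose (5 adjusted over the list alone), with Etv4 at 5.99 and Dusp6 at 2.67 (adjusted p = 0.000308). On the pancreas and bile duct list 4 of 8 rose and 0 fell (4 and 1 adjusted over the list alone), with Sox9 at 2.46 and Cpa1 at 4.93 (adjusted p = 0.00333). On the glycolysis list 4 of 16 rose and 1 fell (10 and 1 adjusted over the list alone), with Pdk1 at 1.35 and Slc2a3 as the faller (adjusted p = 9.09e-06). The hypoxia list also moved up (adjusted p = 0.000923). On the Notch list 1 of 8 rose (4 adjusted over the list alone), the gene being Hey1 at 2.45, which lost its call without 27SS batch 2 (adjusted p = 0.252). For the list as a set, the adjusted p = 0.00268. The ribosomal protein list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 8 had an unadjusted p under 0.05 and 1 passed by DESeq2 (adjusted p = 0.00258). The heat shock list moved down as a set (adjusted p = 0.0361), but 0 of 14 members passed by edgeR (5 at an unadjusted p under 0.05), and 1 rose and 0 fell both adjusted over the list alone and by DESeq2.

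Pancreas-like cells, named from Pdx1, Nkx6-1, Nkx2-2 and other genes, lay mostly in cluster 22 and were fitted in 11 libraries from 12SS, with 1 library, to 27SS. A smaller part, cluster 38, was led by Gcg, with 0 cells at 12SS and 15 of 98 and 21 of 177 at 27SS, at 12080 and 5974 CPM of Gcg, so the rise of Gcg in the class is that of this cluster. Of the 12SS and 15SS cells of batch 2, 296 of 305 and 335 of 409 lay at resolution 2 in a stomach-like cluster with few later cells, so early and late cells differ here too. The next 5 genes had no UMI at 12SS. At 27SS, Gcg, the glucagon gene (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), was at least 1684-fold higher, at 1190 CPM (n = 2), and Cpa1, a pancreatic carboxypeptidase, at least 118-fold higher, at 83.6 ± 0.550 CPM (SD, n = 2). Ptf1a, a transcription factor of the exocrine lineage, was at least 116-fold higher, Kirrel2, an adhesion protein, at least 109-fold, and Pcsk2, a prohormone convertase, at least 96.6-fold. Gcg, Cpa1 and Ptf1a were among the naming markers. Chst2, a sulfotransferase, rose by 7.68 (SE 0.60, adjusted p = 1.19e-06). Spink1 fell by 5.56 (SE 0.62, adjusted p = 2.42e-05), from 422 CPM at 12SS (n = 1) to 4.88 ± 2.27 CPM (SD, n = 2) at 27SS. Emp1, a membrane protein, fell by 4.15. Ero1lb, of oxidative protein folding, fell by 4.01, Ptges, which makes prostaglandin E, by 3.24 and Cd34 by 3.15. Tagln, of the actin cytoskeleton, fell by 3.76 and stood late at 16.2 CPM against 117 CPM in other germ layers. Of 11796 genes, 1105 changed, 517 up and 588 down. Batch 1 alone gave 379 and batch 2 alone 648. Leaving out 12SS batch 2 gave 726, and Tagln lost its call without it (adjusted p = 0.0959). Leaving out 12SS and 15SS of batch 2 gave 1027 and ended the calls of Gcg and Tagln (adjusted p = 0.128 for Tagln).

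Of 26 lists, 13 moved in pancreas-like cells. With an estimated correlation 4 held, at adjusted p = 0.0458 each (0 with batch as a block): Fgf, pancreas and bile duct, retinoic acid and pan-endoderm. The other 9 were lost (adjusted p from 0.0570 to 0.585). On the Fgf list 6 of 12 rose and 0 fell (6 and 1 adjusted over the list alone), with the targets Etv4, Etv5 and Dusp6 at 9.06, 5.21 and 4.44, and Etv1, with no UMI at 12SS, at least 46.0-fold higher (adjusted p = 0.000191). On the pancreas and bile duct list, which shares markers with the class, 6 of 13 rose and 1 fell (9 and 1 adjusted over the list alone), with Nkx6-1 at 4.27 (adjusted p = 4.81e-06). On the retinoic acid list 6 of 12 fell (6 adjusted over the list alone), with Cyp26a1 at -4.43, Stra6, a receptor for retinol carriers, at -2.68, and Dhrs3 at -2.41 (adjusted p = 0.00197). On the pan-endoderm list 0 of 12 rose and 5 fell (1 and 8 adjusted over the list alone), with Gata6 at -1.13 (adjusted p = 8.51e-05). On the cholesterol synthesis list 15 of 17 rose (16 adjusted over the list alone), with Msmo1 at 2.99 and Hmgcs1 at 1.93 (adjusted p = 5.38e-14). Of imprinted growth genes 7 of 13 rose and 1 fell (7 and 1 adjusted over the list alone), with Mest at 3.79, Dlk1 at 3.74 and Igf2r, which clears Igf2, at -1.25 (adjusted p = 0.0187). On the hedgehog list 5 of 8 fell (6 adjusted over the list alone), with Gli3 at -2.04 and Cdon at -1.66 (adjusted p = 0.00197), both lost without 12SS and 15SS of batch 2 (adjusted p = 0.317 and 0.170), as was Gata6 (adjusted p = 0.0647). The junction and keratin, ribosomal protein, early embryonic, glycolysis and Hox 1 to 4 lists also moved down (adjusted p = 0.00197, 4.89e-06, 0.00659, 0.0201 and 0.0440). The G2/M list moved down with 0 of 20 members (0 adjusted over the list alone) passing by edgeR, of which 7 had an unadjusted p under 0.05 and 0 passed by DESeq2 (adjusted p = 0.0205).

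The lists for Bmp and Tgf-beta, apoptosis and oxidative phosphorylation moved in none of the 10 fits by camera. Their lowest adjusted p values were 0.0968, 0.215 and 0.0921.

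**Figure D2:**
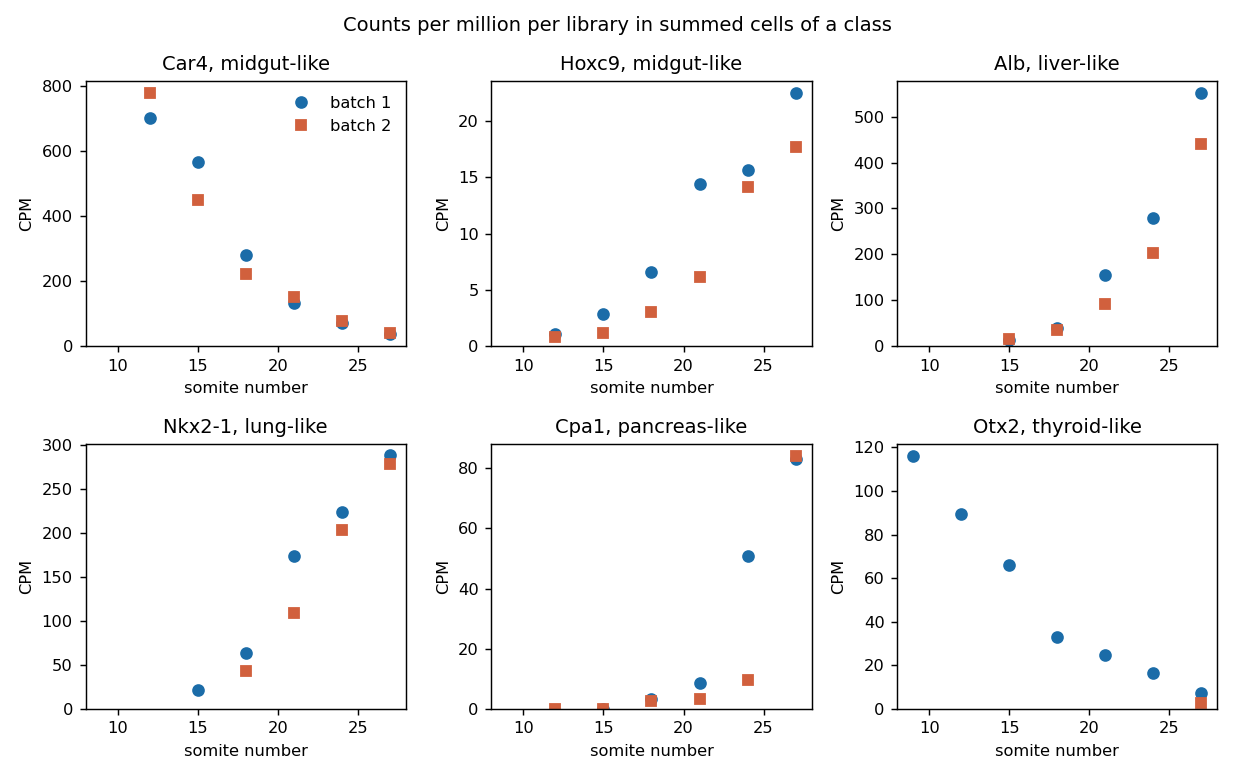
CPM (y axis) against somite number (x axis) for Car4 and Hoxc9 in midgut-like, Alb in liver-like, Nkx2-1 in lung-like, Cpa1 in pancreas-like and Otx2 in thyroid-like cells. Each point is 1 library, a circle for batch 1 and a square for batch 2. At 27SS the 2 libraries of midgut-like Car4 have a mean of 38.5 CPM, against 741 CPM at 12SS.

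A further comparison asks whether the change with stage differs between regions, over each pair of the 4 classes with the most cells. Hindgut-like cells differed from midgut-like cells in 789 of 14352 genes over 7 libraries (471 higher, 318 lower). The difference was 4.10 for Osr1, a zinc finger gene, and -4.34 and -3.37 for Hoxd9 and Hoxb8, which fell in hindgut-like cells. Leaving out 15SS batch 1 gave 240 genes, 27SS batch 1 gave 284, 18SS batch 1 gave 484 and 27SS batch 2 gave 1340. Cells like oesophagus and stomach differed from midgut-like cells in 2134 of 14324 genes over 11 libraries (1209 higher, 925 lower), with Car4 at 2.61 and Serpina1a at -2.83, and in 1123 genes without 12SS batch 2. Pharynx-like against midgut-like cells gave 1759 of 14504 genes over 7 libraries (1250 higher, 509 lower), with Phlda2 at 4.09 and Hoxb9 at -4.19. Leaving out 15SS batch 1 gave 879 and 27SS batch 1 gave 1056.

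Against hindgut-like cells, those like oesophagus and stomach gave 433 of 13478 genes over 6 libraries (172 higher, 261 lower), with the lipid genes Scd1, Mvd and Insig1 at 3.08, 2.60 and 2.56 and Dlk1 at -3.43. There were 119 without 15SS batch 1, 190 without 18SS batch 1, 242 without 27SS batch 1 and 717 without 27SS batch 2, and Mvd lost its call without 15SS batch 1 (adjusted p = 0.0630). Pharynx-like against hindgut-like cells gave 2318 of 14499 genes over 8 libraries (1236 higher, 1082 lower), with Cdkn1a, an inhibitor of the cell cycle, at 3.96 and Hhex at -5.06, and 1087 without 9SS or 1353 without 12SS batch 1. Pharynx-like against oesophagus and stomach-like cells gave 472 of 13398 genes over 6 libraries (281 higher, 191 lower), with Pdgfc, a growth factor, at 2.48 and Sox21 at -2.75. There were 218 without 15SS batch 1, 251 without 18SS batch 1 and 297 without 27SS batch 1. The 4 pairs of hindgut-like or pharynx-like with midgut-like or stomach-like cells rest on 6 or 7 libraries, of which 27SS is the only batch 2 stage.

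Between neighbouring stages, the question is which step shows most change in pooled gut endoderm. No gene passed in any of the 6 steps by edgeR, at 0 of 17474 genes each, so no step gene is named. Genes with an unadjusted p under 0.05 numbered 551 from 9SS to 12SS, 173 from 12SS to 15SS, 184 from 15SS to 18SS, 57 from 18SS to 21SS, 109 from 21SS to 24SS and 170 from 24SS to 27SS. DESeq2 called 26, 5, 4, 0, 1 and 3 genes, and edgeR with batch as a block 24, 1, 1, 0, 0 and 0. The first step has 1 library at 9SS, which is assumed to vary like the others. On data simulated for 15SS to 18SS, the test found 58% of 4-fold and 4% of 2-fold changes.

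Shares of cells show which regions the sorted samples held. Of 21 classes, 3 changed their share with somite number by a 2-sided permutation test with 100000 resamples, over 13 libraries (95% intervals of shares in brackets). Visceral endoderm-like cells, with Cubn, Amn and Apoa4 of the yolk sac endoderm, fell from 7.45% (6.91 to 8.03%) of kept cells at 9SS to 0.492% (0.315 to 0.767%) at 27SS in batch 1, and from 13.1% (12.4 to 13.9%) at 12SS to 0.789% (0.568 to 1.09%) in batch 2. Pearson's r was -0.826 (p = 0.00014, adjusted p = 0.00294) and Spearman's rho -0.920 (p = 4e-05, adjusted p = 0.00084). Without the 2 farthest libraries r was -0.814 (permutation p = 0.00071), within batch 1 -0.971 (exact permutation p = 0.000397, n = 7) and within batch 2 -0.915 (exact permutation p = 0.00556, n = 6). Lung-like cells rose from 0.0136% (0.00240 to 0.0769%) of gut endoderm cells at 9SS to 7.80% (6.81 to 8.91%) at 27SS in batch 1, and from 0.101% (0.0392 to 0.259%) at 12SS to 12.1% (11 to 13.3%) in batch 2. Pearson's r was 0.722 (p = 0.00690, adjusted p = 0.0483) and Spearman's rho 0.759 (p = 0.00348, adjusted p = 0.0244). Without the 2 farthest libraries r was 0.716 (permutation p = 0.0180), within batch 1 0.960 (exact permutation p = 0.00119, n = 7) and within batch 2 0.777 (exact permutation p = 0.111, n = 6). The call of lung-like cells was lost without any 1 of 10 libraries (r from 0.671 to 0.821 over the 13), and kept without 18SS batch 2, 21SS batch 2 or 27SS batch 1. Gut endoderm cells of no named region fell from 56.5% (55.4 to 57.6%) at 9SS to 8.59% (7.56 to 9.75%) at 27SS in batch 1, and stood at 10.6% (9.65 to 11.6%) at 12SS and 6.77% (5.91 to 7.74%) at 27SS in batch 2. Pearson's r was -0.695 (p = 0.00262, adjusted p = 0.0275) and Spearman's rho -0.648 (p = 0.0189, adjusted p = 0.0795). Without the 2 farthest libraries r was -0.560 (permutation p = 0.0502), within batch 1 -0.889 (exact permutation p = 0.00119, n = 7) and within batch 2 -0.459 (exact permutation p = 0.361, n = 6). The relation no longer held without the 2 farthest libraries, so it rests on them. Its call was lost without 9SS (r = -0.564), 12SS, 21SS or 24SS of batch 1, or 24SS or 27SS of batch 2. The other 18 classes did not pass (adjusted p from 0.0622 to 0.949). With batch as a block 12 classes passed, these 3 and 9 others: surface ectoderm-like (blocked adjusted p = 0.00084, r = 0.939 and 0.873 within batches 1 and 2), pharynx-like (0.00486, 0.922 and 0.764), neural (0.00486, 0.855 and 0.831), neural crest (0.00567, 0.340 and 0.947), cardiomyocyte (0.00667, -0.133 and -0.837), liver-like (0.0329, 0.472 and 0.879), midgut-like (0.0486, 0.864 and -0.0510), intermediate mesoderm (0.0486, 0.647 and 0.631) and primordial germ cell-like (0.0486, -0.924 and 0.628). The batches went opposite ways in the last and in midgut-like cells. Without the block 5 passed without 27SS batch 1. Only 1 passed without 9SS, 12SS, 21SS or 24SS of batch 1, or 24SS or 27SS of batch 2.

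**Figure D3:**
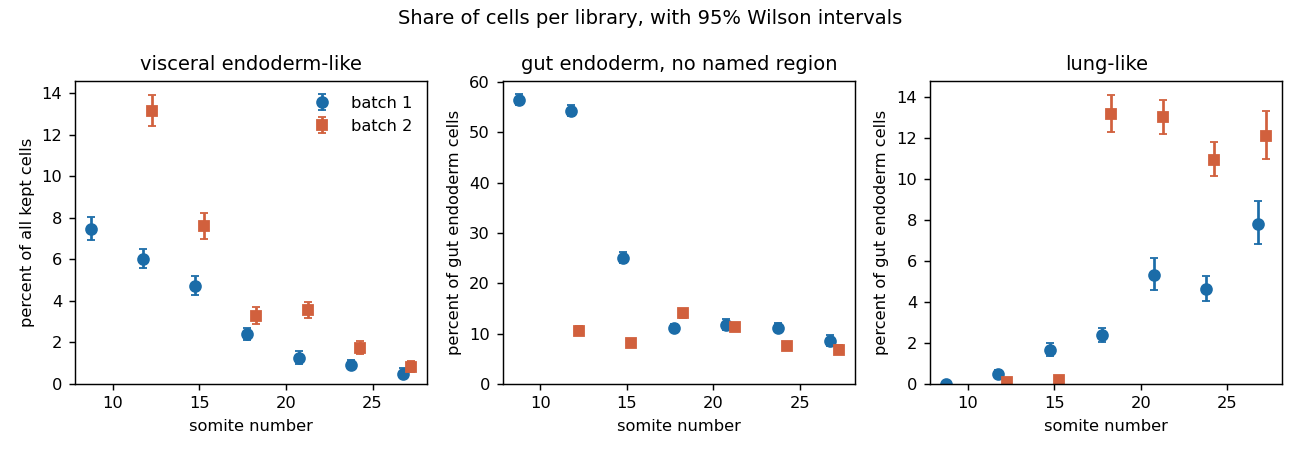
Share of visceral endoderm-like cells among all kept cells, and of gut endoderm cells of no named region and lung-like cells among gut endoderm cells (y axes, percent), against somite number (x axis). Each point is 1 library, a circle for batch 1 and a square for batch 2, and bars are 95% Wilson intervals of counting error. Visceral endoderm-like cells end at 0.492% and 0.789%.

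The last comparison sets the batches side by side within each of 6 stages, to measure how far repeats of a stage differ. The batches held different tissue. At 12SS and 15SS of batch 2 there were no pharynx-like or thyroid-like cells, and lung-like cells made up 0.101% and 0.171% of gut endoderm cells (13.2% at 18SS) and bile duct-like cells 21.1% and 19.9% (4.88% at 18SS). The rise of lung-like cells in batch 2 rests on these 2 libraries, and other class trends do in part. At 27SS (95% intervals in brackets), of gut endoderm cells 22.9% (21.3 to 24.6%) in batch 1 and 3.19% (2.62 to 3.90%) in batch 2 were pharynx-like, and 14.7% (13.3 to 16.1%) and 2.03% (1.57 to 2.60%) were hindgut-like. Of all kept cells, 31.3% (29.8 to 32.7%) and 8.07% (7.30 to 8.90%) were surface ectoderm-like, and 0.0259% (0.00457 to 0.146%) and 17.2% (16.1 to 18.3%) mesoderm-like. Over stages the last made up 15.9 to 26.3% in batch 2 and 0.0119 to 0.604% in batch 1. An Epcam UMI was seen in 9.69 to 16.6% of cells per mesoderm-like cluster (median UMIs 6324 to 16720), near the 13.1% of the endothelium cluster (median 17330), against 99.3% in midgut-like cluster 0 (median 13620). The labels give 1 protocol for all libraries and no gate, so a different sort in batch 2 stays open, and shares of kept cells depend on it. In pooled gut endoderm, posterior genes were lower in batch 2: Hoxd11 by 8.06, Hoxc10 by 7.12 and Cdx4 by 5.40 (SE 0.22, adjusted p = 6.42e-07), with 41.1 CPM in batch 1 and 1.00 CPM in batch 2 (n = 6 each). Fgf8, a ligand of the tail end and pharynx, was lower by 4.88, Rspo3, which boosts Wnt signalling, by 4.53 and Foxe1, of the thyroid and pharynx, by 4.25. Higher in batch 2 were Rpl10-ps3 and Rps27rt, copies of ribosomal protein genes, by 1.65 and 1.57, Wdr89 by 1.59, Reln, a matrix protein, by 1.57, Nme2, a nucleoside diphosphate kinase, by 1.49 and Usp50 by 1.47. Of 17012 genes, 6904 differed over 12 libraries, 3357 higher and 3547 lower in batch 2. Leaving out 24SS batch 2 or 24SS batch 1 gave 4548 or 4564. With somite number, batch and the software version of the file header in a fit of 13 libraries, 3116 differed by batch and 414 by version.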

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

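The tests of the pooled and batch counts against other splits, the rule on too few UMIs and the choice of 6 of 16 genes were made after their results were seen. The other tests of patterns were chosen once the patterns were seen, with predictions written before they were run. The 6 pairs of classes were set in advance.

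The change with stage differed between classes by a test of the interaction itself in each of the 6 pairs below. Values are differences in log2 change, the class named first less the other.

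Hindgut-like cells differed from midgut-like cells in 789 genes. The named genes were Osr1 (4.10), Dapl1 (3.74), Fzd7 (3.14), Car4 (3.04), Npnt (2.93), Hoxd9 (-4.34), Stmn2 (-3.82), Hoxb8 (-3.37), Hoxaas3 (-3.31) and Hoxa7 (-2.96). At the adjusted p given, Dapl1 lost its call without 15SS (0.0650) or 27SS (0.0505) of batch 1. Hoxaas3 lost it without 15SS (0.151), 18SS (0.0832), 21SS (0.0578) or 27SS (0.173) of batch 1.

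Oesophagus and stomach-like cells differed from midgut-like cells in 2134 genes. The named genes were Car4 (2.61), Ly6h (2.18), Ckb (1.91), Ptn (1.86), Ackr3 (1.76), Serpina1a (-2.83), Serpina1b (-2.74), Cpne8 (-2.68), Car8 (-2.52) and Ripply3 (-2.47).

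Pharynx-like cells differed from midgut-like cells in 1759 genes. The named genes were Phlda2 (4.09), Rarres1 (3.49), Cdkn1a (2.97), Pmp22 (2.72), Car4 (2.68), Hoxb9 (-4.19), Hoxb8 (-3.21), Pnliprp1 (-3.01), Car8 (-2.73) and Cpne8 (-2.67). At the adjusted p given, Pnliprp1 lost its call without 12SS (0.403), 18SS (0.0538), 21SS (0.0514) or 24SS (0.0680) of batch 1. It did too without 27SS of batch 1 (0.106) or 2 (0.0503). Hoxb8 lost its call without 15SS batch 1 (0.0875).

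Oesophagus and stomach-like cells differed from hindgut-like cells in 433 genes. The named genes were Hoxaas3 (4.89), Uap1l1 (3.63), Scd1 (3.08), Mvd (2.60), Insig1 (2.56), Maf (-5.19), Robo2 (-3.72), Dlk1 (-3.43), Upp1 (-3.32) and Mreg (-3.27). Calls ended without 15SS batch 1 for Hoxaas3, Mvd, Maf and Mreg (adjusted p = 0.0951, 0.0630, 0.0751 and 0.0553). Without 18SS batch 1 they ended for Hoxaas3 and Maf (0.0540 and 0.0675), and without 27SS batch 1 for Uap1l1 (0.0716).

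Pharynx-like cells differed from hindgut-like cells in 2318 genes. The named genes were Cdkn1a (3.96), Rarres1 (3.67), Hoxb3os (3.29), Phlda2 (3.13), Crabp1 (2.75), Hhex (-5.06), Tmem100 (-4.93), Prrx1 (-4.33), Dapl1 (-4.29) and Upp1 (-3.68). A call ended, at the adjusted p given, for Rarres1 (0.0780 without 12SS batch 1).

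Pharynx-like cells differed from oesophagus and stomach-like cells in 472 genes. The named genes were Pax1 (2.98), Cyp26b1 (2.51), Robo2 (2.50), Pdgfc (2.48), Pmp22 (2.33), Sox21 (-2.75), Scd1 (-2.27), Nsdhl (-2.19), Sp5 (-2.17) and Has2 (-2.11). Calls ended without 15SS batch 1 for Pax1 and Pmp22 (adjusted p = 0.230 and 0.0508), and without 24SS batch 1 for Pax1 (0.0635). Without 18SS batch 1 they ended for Pax1, Pmp22 and Cyp26b1 (0.0572, 0.205 and 0.0572). Without 27SS they ended for Pax1 and Cyp26b1 in batch 1 (0.0630 and 0.131) and Pax1 and Pmp22 in batch 2 (0.0809 and 0.114).

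Gcg rose with stage in midgut-like cells, with no UMI at 12SS and 1.34 CPM at 27SS (at least 12.5-fold higher), and also in oesophagus and stomach-like and hindgut-like cells. Free RNA would give a like level in all cells of a library: from 18SS on, the ratio of midgut-like cells to cells of other germ layers had a median of 0.691 over 8 libraries (range 0 to 2.11), 0.351 in oesophagus and stomach-like and 1.36 in hindgut-like cells, so free RNA may be the source. Endocrine cells inside the class would carry Pcsk2 with Gcg: the ratio of the Gcg to the Pcsk2 fraction was 0.665, but Pcsk2 had 0 to 3 UMIs per library, so this source cannot be told apart. A low expression in the gut cells themselves stays open and was not tested.

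Posterior Hox genes rose with stage in midgut-like cells (median log2 change 4.37 for paralogues 9 to 13). A changing mix of clusters would leave little change within them, but the lowest ratio of the change within a cluster to that in the class was 0.932 over clusters 0 and 15, while cluster 6 had no member past the filter and cluster 16 too few libraries. Hindgut-like cells in the class would bring their other genes, but 20 genes high in hindgut-like cells had a median change of 0.42 (quartiles -1.02 to 1.03), 0.0965 of that of the Hox genes. RNA of other germ layers would bring their markers, but these stood at 0.0124 of the fraction of the Hox genes, at 0.532 to 2.44% against 68.1 to 251% of their level there. As a hypothesis, midgut-like cells may gain posterior Hox expression, but hindgut-like cells, a mix of finer clusters and an untested shift of the dissected region stay open.

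Copies of ribosomal protein genes differed between batches. Of 16 genes tested, 15 copies by name and Wdr89 added by hand, 6 were higher in batch 2 (Rps2-ps6, Rpl10-ps3, Rps27rt, Wdr89, Rpl7a-ps5 and Rpl9-ps6, median log2 difference 1.62) and 5 lower. Tissue content would make the difference smaller within 1 class, but within midgut-like cells it was 0.977 of that in pooled cells. The software version of the headers may be the source: the batch 1 libraries with the older version lay at the level of batch 2, at -0.0986 of the distance of the other batch 1 libraries. Over all 16 genes, before the 6 were chosen, that ratio was -0.417. The batch itself is not excluded for other genes, and no biological explanation was tested.

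Random orders of stage rarely reached the pooled stage count, under the 5% rule: 2 of 100 permutations of stage over the 13 libraries gave as many genes, the real one with 2416 included. The other, with 3645, put later stages in batch 1 (correlation of stage with batch -0.604) and points to the batches as a structure of the samples, with 4316 genes in the real order with batch as a block. With stages permuted within each batch, 1 of 100 gave as many genes, the real order, and the highest other gave 0, or 1 with the block. Of the 32 swaps of batch within stages, 1, the real one with 6904 genes, gave as many, and the highest other gave 0.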

How the results depend on the processing

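The alternatives chosen after seeing the data are each batch alone, the software version of the header as a block or a term, and leaving out the 12SS and 15SS libraries of batch 2. Causes of a change were not tested unless said.

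Of the 676 genes named in class fits, 6034 of 6563 values kept their direction and side of the threshold over alternatives other than leaving out 1 library, and 527 lost the call. For the 75 pooled genes 909 of 972 values kept theirs, and for the 12 batch and 60 interaction genes all 48 and 120. With 1 library left out, 5818 of 6444 class values, 899 of 971 pooled values, 419 of 450 interaction values and all 144 batch values kept theirs. Direction turned in 4, none of them called under the alternative: pooled Fga over all kept cells (-1.22, adjusted p = 0.45), pooled Sox17 in batch 2 alone (0.52, adjusted p = 0.106), and Pax9 and Hoxb1 of oesophagus and stomach-like cells in batch 1 alone (0.78, adjusted p = 0.694, and 1.56, adjusted p = 0.123). RLE factors, no filter on low counts, doublets kept and the stricter filter moved no count of genes by over 1.5 times.

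Counts of genes with batch as a block were 4316 in pooled gut endoderm and 1065 in bile duct primordium. With an equal number of cells per library, which lowers depth, they were 1237 in midgut, 410 in hindgut, 278 in pharynx, 413 in oesophagus and stomach, 574 in liver, 770 in lung, 527 in thyroid, 344 in bile duct primordium and 541 in pancreas. With the header's version as a block they were 3610 in hindgut, 2253 in pharynx, 1853 in oesophagus and stomach, 3246 in thyroid, 1065 in bile duct primordium and 1674 in pancreas. Batch 1 alone, with fewer libraries, gave 372 in oesophagus and stomach, 632 in lung and 379 in pancreas. Batch 2 alone gave 1229 in pooled gut endoderm, 1348 in midgut, 576 in oesophagus and stomach, 1212 in liver and 648 in pancreas. Without the 12SS and 15SS libraries of batch 2 there were 1724 in bile duct primordium. Steps from 9SS to 18SS gave 24, 1 and 1 with the block and 26, 5 and 4 by DESeq2. Those from 21SS to 27SS gave 1 and 3 by DESeq2. The batch difference with somite number and version in the fit gave 3116 genes.

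Lists numbered 13 in pooled with batch as a block, and 4 in pancreas and 0 in each other fit with an estimated correlation. By fry they were 11 in midgut and 13 in liver. Without the 12SS and 15SS libraries of batch 2 there were 11 in midgut and 5 in bile duct primordium. For shares, classes passing numbered 6 at resolution 0.5, 7 at resolution 2, 1 clustered without stage genes and 6 with the stricter filter. They numbered 12 with the block and 5 without 12SS and 15SS of batch 2. Clustering without stage genes gave r = -0.568 in gut endoderm of no named region, and leaving out those libraries 0.668 in lung. No lung-like class formed at resolution 0.5 or without stage genes, so there is no value for it there.

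Leaving out 1 library at a time, counts of genes ran from 1504 to 2487 in pooled gut endoderm, 1236 to 2718 in hindgut, 804 to 1685 in pharynx, 407 to 1084 in oesophagus and stomach, 1116 to 2735 in liver, 565 to 2364 in lung, 1112 to 2511 in thyroid, 221 to 524 in bile duct primordium and 726 to 1163 in pancreas. For pairs of classes they ran from 240 to 1340 in hindgut against midgut, 1123 to 2338 in oesophagus and stomach against midgut, 879 to 1805 in pharynx against midgut, 119 to 717 in oesophagus and stomach against hindgut, 1087 to 3137 in pharynx against hindgut and 218 to 681 in pharynx against oesophagus and stomach. The batch difference ran from 4548 to 7214 genes, lists from 5 to 11 in oesophagus and stomach, 7 to 12 in lung and 5 to 12 in thyroid, and shares from 1 to 5 in the number of classes, 0.671 to 0.821 in lung and -0.796 to -0.564 in gut endoderm of no named region. Where a stage was left with 1 library, that library is assumed to vary like the others. Classes weighted equally were not run, as no named class had the 50 cells needed in every library. Depth limits the counts of class fits, as the equal number of cells shows. Data simulated at these depths gave 3% of 2-fold and 53% of 4-fold differences of stomach-like against midgut-like cells, with depth not varied. These data took the spread of the pooled fit for both classes. With the spread of the class itself, stage fits found 92% of 2-fold changes in midgut-like and 74% in oesophagus and stomach-like cells. The 3% and 53% therefore do not measure how many differences the interaction test finds.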

Other observations

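All tests of stage in the classes below were chosen after the classes were seen.

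Visceral endoderm-like cells, 4300 in 11 libraries from 9SS to 24SS, were named from markers that include Apoa4, Apob, Cubn, Amn and Rhox5. They lay in clusters 17 and 28, and cluster 28 held 713 of 1048 at 12SS and 20 of 128 at 24SS of batch 2, so the mix of clusters shifted. Sycn, a secretory granule protein, rose by 4.62 (SE 0.59, adjusted p = 0.00240), from 3.16 to 103 CPM. Igfbp1 rose by 3.70, Serpina1c by 3.33, Tff3 by 3.02, Sema3c by 2.90 and Rbp2 by 2.77. Oat fell by 1.83, Sct by 1.80, Car4 by 1.78, Emb by 1.71, Slc16a1 by 1.70 and Fth1 by 1.66. Of 12418 genes, 403 changed (256 up, 147 down), 2902 with batch as a block and 982 by DESeq2. With 1 library left out there were 177 and 197 (12SS, batches 1 and 2), 265 and 263 (18SS) and 194 and 193 (21SS). There were 237 and 78 (24SS), 230 (15SS batch 1) and 272 to 371 without any other. Cells like primordial germ cells, 1011 in 8 libraries, raised Rhox6 by 2.73 (SE 0.33, adjusted p = 0.00161), from 33.4 to 226 CPM. Batch 1 gave 9SS to 18SS and batch 2 15SS to 24SS, so stage is mixed with batch. Ldhb, lactate dehydrogenase B, rose by 2.57, Rhox5 and Rhox9 by 2.25 and 1.56, Gstm3 by 2.18 and Pecam1, an adhesion protein, by 1.68. Msx1, a target of Bmp signalling, fell by 3.17, Id1, another, by 2.38, Rspo3 by 2.74, Ccnd2, a cyclin, by 1.92, Sct by 3.07 and Fkbp11 by 2.58. Of 9420 genes, 147 changed (62 up, 85 down) and 262 by DESeq2. With batch as a block 0 did, and 745 had an unadjusted p under 0.05. With 1 library left out there were 20 (9SS batch 1), 48 (12SS batch 1), 366 (15SS batch 2), 48 (21SS batch 2) and 68 (24SS batch 2), and 118 to 202 without any other.

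Surface ectoderm-like cells, 12162 in 13 libraries, also carry Epcam. Their 5 clusters differed by library: cluster 32 held 118 of 128 at 12SS batch 2 and 17 of 1208 at 27SS batch 1. Ckb, creatine kinase, rose by 2.78 (SE 0.46, adjusted p = 0.00707), from 8.46 to 69.1 CPM. Hspb1 rose by 2.60, Tshz2, a zinc finger gene, by 2.42, Mfap4 by 2.39, Hoxb3os by 2.19 and Cldn3 by 2.14. Phlda2 fell by 2.95, Ifitm1 by 2.65, Greb1l by 1.94, Emb by 1.73, Prtg, protogenin, by 1.68 and Nr6a1, a nuclear receptor of the early embryo, by 1.56. Of 12681 genes, 243 changed (168 up, 75 down), 1124 with batch as a block and 718 by DESeq2. With 1 library left out there were 112 (9SS batch 1), 86 (12SS batch 1), 144 (15SS batch 1), 155 (18SS batch 1), 144 (21SS batch 1), 62 (27SS batch 1) and 99 (27SS batch 2), and 182 to 264 without any other. Mesoderm-like cells, 8222 in the 6 batch 2 libraries, raised Aes, a Groucho-related repressor, by 2.91 (SE 0.35, adjusted p = 0.00934), from 13.1 to 91.2 CPM. Nfib, a transcription factor, rose by 2.58, Oxct1 by 2.21, Nkx2-3 by 2.13, Nrk by 2.10 and Cxcl13, a chemokine, by 2.10. Ttr fell by 3.34, Phlda2 by 3.08, Nr6a1 by 2.50, Car4 by 2.48, Stard8 by 2.11 and Rbp4, which carries retinol in blood, by 2.05. Of these, Ttr, Car4 and Rbp4 are also endoderm genes, visceral endoderm-like cells became fewer in these libraries, and free RNA was not tested. Of Hox paralogues 9 to 13, 7 of 8 members rose (adjusted p = 6.86e-07, and adjusted p = 0.494 with an estimated correlation). Of 13864 genes, 409 changed (253 up, 156 down) and 816 by DESeq2. With 1 library left out there were 9 (12SS), 166 (15SS), 704 (18SS), 262 (21SS), 96 (24SS) and 41 (27SS).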
